A study of Mus musculus with 15 samples.

How the data were processed

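CD45+ cells that were single and negative for the dead-cell dye DAPI were sorted from the cortex and hippocampus of 5XFAD mice with human APOE2, APOE3 or APOE4 in the mouse Apoe locus, 5 libraries per genotype, at 60 weeks of age. Per the labels' protocols, mice were perfused, tissue was digested with collagenase and cleared of debris on a Percoll density step, and RNA from cells sorted into lysis buffer went into a SMART-seq low-input preparation, which amplifies full-length complementary DNA from few cells. Reads were quantified with Salmon against mm10, per the submitters' processing notes. The version of Salmon, its settings, the read length and the annotation release are not given in the sources used here.

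Each library had 1 table of 116546 transcripts. Per the file headers, the columns were transcript length, effective length in bases, TPM (transcript abundance scaled to a fixed library total) and the estimated count of reads per transcript. The deposited estimated counts need not be whole, and 90.5% of nonzero values lay more than 0.0005 from a whole number. The deposited TPM values, which per the file headers are already scaled for length and depth, were not used for tests. The deposited effective lengths entered only 1 alternative. Transcripts were matched by identifier to GENCODE M21 on mm10, which matched 115977 of them to 35498 genes. The 569 unmatched transcripts held 0.075 to 0.09% of reads per library and were left out. The transcripts counted were mouse sequences, and 21794 of the genes were protein-coding. Human APOE and Xist were not among them, and strand use in counting is not given in the sources used here.

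Estimated counts were summed per gene and rounded to whole numbers. Genes were kept by edgeR's filterByExpr with its defaults (minimum count 10, minimum total 15), which left 15027. Library totals over genes were scaled by TMM. One model with 1 coefficient per genotype was fitted to all 15 libraries with edgeR 4.0.16 in R 4.3.3 (robust quasi-likelihood, 12 residual degrees of freedom), and the 3 contrasts were E4 against E3, E2 against E3 and E4 against E2. The tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The biological coefficient of variation was 0.222, and 0.097 at high expression. CPM values are TMM-scaled, means carry the SD over 5 libraries, and the SE of a log2 fold change was derived from its F statistic. Libraries held 38.1 to 49.1 M (mega) estimated reads.

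39 gene lists of microglial states, metabolic and stress pathways, other cell types, sample quality, Apoe neighbours and sex chromosomes were fixed before the data were examined, as were the contrasts, the tests and most alternatives. A list on nuclear-retained RNA had fewer than 5 measured members, so 38 were tested. Members that rose or fell are those past the threshold by edgeR, over all genes and adjusted over the list alone. A list's level is the mean log2 CPM (prior count 2) of its members in a library. Levels were compared by the exact two-sided permutation test over all 252 arrangements of 5 against 5, adjusted over the 38 lists of a contrast. limma 3.58.1 camera, with a preset correlation of 0.01 and with an estimated one, compared each list with all other genes, and fry tested whether its members moved together. Several lists hold genes that other cell types of the sort also express, such as Apoe, Cybb and the cathepsins.

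Genes named in the text follow a rule fixed with the lists. It takes the 10 smallest p-values in each direction per contrast with an official symbol, up to 4 members with the smallest p of each list described, and 16 genes named whatever their p, of which Xist was not counted and 1 other is not reported here. Genes of chromosome Y were read apart. Azurophil and specific granule genes, mature neutrophil receptor genes, haemoglobin, early B-lineage and stem-cell or megakaryocyte genes, and genes near-absent in 1 genotype, were chosen later, and the text says so where they appear.

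Alternatives were DESeq2 1.42.0 size factors and Wald test, limma voom with quality weights, no filter and a stricter one (1 CPM in 10 libraries), effective-length offsets, protein-coding genes only, only the 10 libraries compared, the replicate number as a block, and a covariate that is the mean level of the T cell, B cell, neutrophil, monocyte and border-associated macrophage lists. For lists and levels they were also estimated correlation, fry, a prior count of 0.5 and the median of members. Each library was left out in turn. Chosen after seeing the data were a covariate of 4 Y-linked genes, the libraries numbered 2 to 5 only, and leaving out immunoglobulin and T cell receptor segments.

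The gene test was tested on simulated data drawn from each gene's mean over all libraries, its fitted dispersion and the library sizes, with 14812 genes tested. The 200 genes changed were drawn from those with a mean over 1 CPM, so recovery below that was not measured. The test recovered 85 of 100 genes changed 2-fold and 62 of 100 changed 1.5-fold in E4 against E3, with 6 false calls there. It made 0 calls in E2 against E3, where nothing was changed. In the same kind of test of lists, the 1 list moved was called and 0 others were. The simulated genes were drawn independently of each other, while estimated correlations within the real lists reached 0.839. That test therefore cannot show how often camera with a preset correlation makes false calls on these lists. Other splits of the 10 libraries of a contrast into 5 and 5 were refitted 100 times of the 126 possible, the real one included. No replicate pair held equal values: over 30 pairs within genotypes, r ran from 0.965 to 0.98 and the mean chi-square per gene from 16 to 117.7.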

Results

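Messenger RNA was profiled in CD45+ cells, the leukocytes and microglia of the brain, sorted from the cortex and hippocampus of 60-week-old 5XFAD mice. 5XFAD is a transgene that drives amyloid plaque formation, and these mice carried 1 copy. In place of mouse Apoe they carried, on both alleles, a human APOE sequence of the E2, E3 or E4 type. E4 raises and E2 lowers the risk of Alzheimer disease in people, and E3 is the usual reference. There were 15 libraries, 5 of each genotype. Summed estimated reads, in M (mega), were 43.1, 38.2, 39.5, 46.0 and 44.8 in E2 libraries 1 to 5. They were 43.6, 46.3, 40.3, 49.1 and 44.9 in E3, and 40.9, 42.3, 38.1, 38.9 and 42.1 in E4. The genotype means were 42.3 ± 3.4, 44.8 ± 3.3 and 40.5 ± 1.9 M for E2, E3 and E4 (SD, n = 5 each). Nothing in the labels says whether the 5 libraries of a genotype came from separate mice, so every p-value measures only the spread between these libraries, which may be technical.

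Reads assigned to mouse Apoe (chromosome 7, 19696109 to 19699188, mm10) were found in every library, though its sequence was replaced. In CPM (counts scaled to a fixed library total, with TMM factors), libraries 1 to 5 of E2 gave 14, 24.4, 25.8, 37 and 30.9, those of E3 gave 12.7, 18.6, 15.1, 17.3 and 20.3, and those of E4 gave 7.5, 10.3, 10.4, 10.5 and 10.2. Human APOE was not among the transcripts counted, so the replaced locus was seen only through reads assigned to the mouse gene. A change in these reads need not be a change in expression of either gene. The assigned value was lower in E4 than in E3 by a log2 change of -0.78 ± 0.20 (SE, adjusted p = 0.0112), with all 5 E4 libraries below all E3 libraries. In E2 against E3 it was 0.65 ± 0.19 (adjusted p = 0.0297). That last call rested on single libraries. Adjusted p was 0.0876 without E2 replicate 4, 0.0755 without E2 replicate 5, 0.0588 without E3 replicate 1, 0.0771 without E3 replicate 3 and 0.0544 without E3 replicate 4. It was also 0.0629 by limma voom, 0.0608 with only the 10 libraries compared and 0.123 with a Y-linked covariate.

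The libraries lay apart by genotype. The labels name no batch or litter, so a difference between genotypes cannot be told apart here from one between such groups. The first principal component held 32.3% of the variance and placed E2 between -55.3 and -35.8, E3 between -15.9 and 2.4, and E4 between 45.5 and 55.1. The second held 11.7% and set E3, at -35.5 to -32.2, apart from E2 and E4, at 8.7 to 29.7. Of 15027 genes tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2389 changed in E4 against E3, 2340 in E2 against E3 and 5730 in E4 against E2. Against E3, E4 had 1287 genes higher and 1102 lower, and E2 had 948 higher and 1392 lower. E4 had 3007 higher and 2723 lower than E2. Mitochondrially encoded genes, a sign of library quality, moved with genotype too: their level was lower in E4 by -0.70 against E3 (exact two-sided adjusted p = 0.0464) and by -1.37 against E2 (exact adjusted p = 0.0251). Camera gave adjusted p = 0.371 and adjusted p = 0.479 with an estimated correlation. Against E3 the adjusted p was 0.0532 to 0.0754 in 8 of the runs that leave out 1 library. The library numbered 1 of each genotype stood apart in several gene groups. With only the libraries numbered 2 to 5, a choice made after seeing the data, the counts were 2343, 2606 and 5403. A covariate built from the levels of 5 non-microglial leukocyte lists left 1745, 896 and 1125 genes. A covariate from 4 Y-linked genes, also chosen after seeing the data, left 1262 in E2 against E3, and limma voom called 4194 in E4 against E3.

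The comparison of E4 with E3 asks what the risk allele does to brain leukocytes in this amyloid model. Genes of the disease-associated microglia state, which microglia switch on around plaques, fell in E4. Cst7, a cathepsin inhibitor and a marker of that state (chromosome 2, 150570415 to 150578944), fell from 265.8 ± 78.6 CPM in E3 to 42.7 ± 5.2 in E4 (SD, n = 5 each), a log2 change of -2.64 ± 0.28 (SE, adjusted p = 1.84e-05). Spp1, which encodes osteopontin (chromosome 5, 104435118 to 104441050), fell from 168.8 ± 71.1 to 33.7 ± 9.3 CPM (-2.33 ± 0.53, adjusted p = 0.0095). Trem2, the lipid receptor that the state depends on (chromosome 17, 48346401 to 48354147), fell from 1051 ± 89.6 to 728.2 ± 102 CPM (-0.53 ± 0.09, adjusted p = 0.000687). Itgax fell from 96.7 to 48.4 CPM and Clec7a from 158.2 to 102.2 CPM (adjusted p = 0.00503 and 0.0149). The cathepsin genes Ctsl (725.1 to 412.6 CPM) and Ctsb (5691 to 4017 CPM) and the phosphate exporter gene Ank (139.2 to 52.3 CPM) fell as well. Of 35 disease-associated microglia genes, 26 fell and 0 rose, and 28 fell when adjusted over the list alone. All 5 E4 libraries had a lower mean level of the list, 6.72 ± 0.12 log2 CPM against 7.70 ± 0.26 in E3, a difference of -0.98 (exact two-sided permutation test, adjusted p = 0.0302). The camera test gave adjusted p = 0.153 with an estimated correlation. Without E4 replicate 2, 3 or 4 the exact adjusted p was 0.0603, and without E4 replicate 5 it was 0.0548. The difference was -0.98 or lower in each of these runs, and 4 libraries against 5 cannot give an unadjusted p under 0.0159. The median in place of the mean of the members turned the direction, to 0.05 higher in E4 (exact adjusted p = 0.804). In the library numbered 1, the list stood at 7.50 in E2, 7.24 in E3 and 6.52 in E4, below 8.28 to 8.37, 7.72 to 7.89 and 6.75 to 6.81 in the others. With libraries 2 to 5 only, 27 members fell.

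Genes that mark resting microglia moved less. Of 24 homeostatic microglia genes, 3 fell and 0 rose in E4 against E3, and 2 fell when adjusted over the list alone. P2ry12 was 2499 CPM in E4 and 2457 in E3 (log2 change 0.02, adjusted p = 0.94), and Tmem119 was 2960 and 3243 CPM. The list level was 9.30 ± 0.27 in E4 and 9.46 ± 0.15 in E3 (exact adjusted p = 0.335, camera adjusted p = 0.753 with an estimated correlation). E4 library 1 stood at 9.78, above 9.17 to 9.19 in the other 4, and E3 library 1 at 9.72, above 9.36 to 9.41. Without E4 replicate 2, 0 members fell by edgeR. Without E4 replicate 1, 11 members fell and the level differed by -0.28 (exact adjusted p = 0.0251). With libraries 2 to 5 only, 12 members fell.

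**Figure D1:**
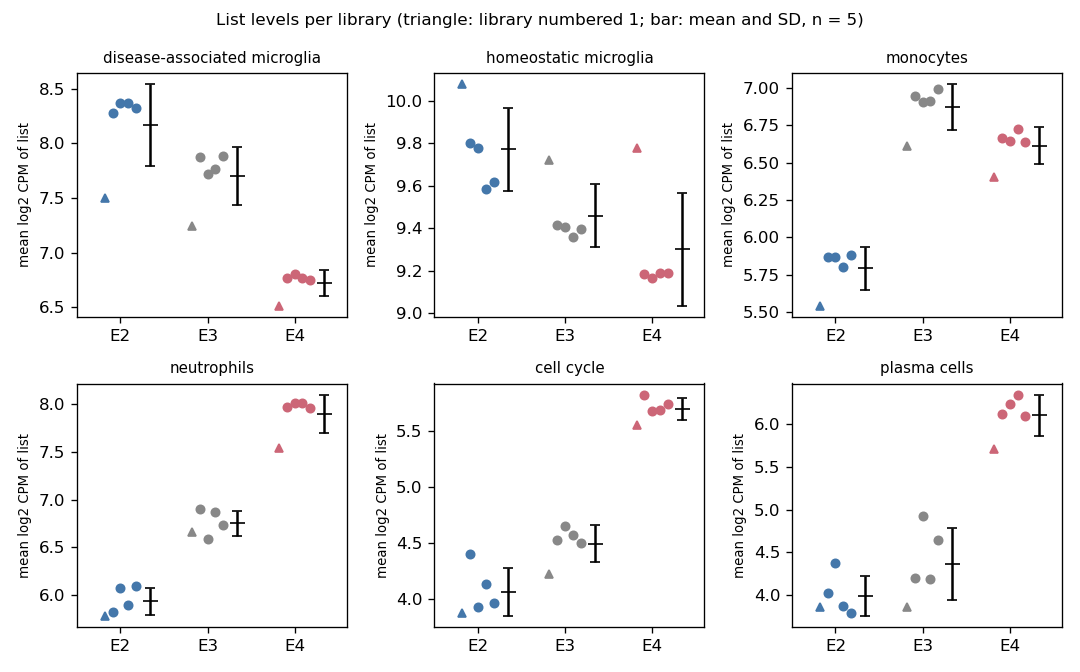
Mean log2 CPM of the members of 6 gene lists in each library of E2, E3 and E4. The triangle marks the library numbered 1 of each genotype, and the bars give the mean ± SD (n = 5); disease-associated microglia genes averaged 6.72 in E4 and 7.70 in E3.

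Lysosomal and class I antigen-presentation genes fell beside the microglial state, and class II genes went both ways, with 5 of 14 higher and 2 lower (3 higher in 8 runs that leave out 1 library). Of 34 lysosome genes, 17 fell and 0 rose in E4 against E3, and 18 fell when adjusted over the list alone. Examples are Mcoln1, a lysosomal ion channel gene (148.9 to 105.6 CPM), Glb1 (106.5 to 76.0 CPM) and Hexa (1190 to 899.4 CPM). The lysosome level fell by 0.33 log2 (exact adjusted p = 0.0302, camera adjusted p = 0.153 with an estimated correlation), and 8 members fell under the leukocyte covariate. Of 17 antigen presentation class I genes, 13 fell and 0 rose, 15 of them fell when adjusted over the list alone, and B2m, the light chain of class I molecules, went from 2716 to 2032 CPM. Their level fell by 0.28 log2 (exact adjusted p = 0.0302, camera adjusted p = 0.104 with an estimated correlation), and 8 members fell without E3 replicate 2, 3 or 5 or E4 replicate 2 or 5. The inflammatory cytokines and NF-kB list had 11 of 31 members lower, among them Il1b (438.5 to 257.9 CPM) and Relb (65.6 to 45.3 CPM), and 0 higher. Its level did not pass (exact adjusted p = 0.518, camera adjusted p = 0.371 with an estimated correlation). Relb is a neighbour of Apoe on chromosome 7 and was lower in E2 than in E3 too (-0.52, adjusted p = 3.78e-05 by edgeR). Of 20 LXR targets and cholesterol efflux genes, 6 fell and 0 rose, led by Nr1h3, which encodes a sterol-sensing receptor (15.1 to 5.9 CPM, a log2 change of -1.37). That list's level fell by 0.31 (exact adjusted p = 0.0302, camera adjusted p = 0.0756 with an estimated correlation), and 10 members fell without E4 replicate 1. The median of its members differed by -0.12 (exact adjusted p = 0.0754).

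Genes of dividing cells, neutrophils and antibody-secreting cells rose in E4. All 33 cell cycle genes measured rose against E3, with Rrm2, a subunit of ribonucleotide reductase, at 128.7 ± 13.8 CPM in E4 and 43.3 ± 5.3 in E3 (1.57 ± 0.12, adjusted p = 1.2e-07) and Birc5 at 42.0 and 13.9 CPM. The cell cycle level rose by 1.20 log2 (exact adjusted p = 0.0302, camera adjusted p = 0.037 with an estimated correlation). Of 25 neutrophils genes, 20 rose and 2 fell. Ngp, a granule protein gene (chromosome 9, 110419747 to 110423012), rose from 2109 ± 333 to 6938 ± 508 CPM (1.72 ± 0.10, adjusted p = 4.46e-09), Ltf from 1315 to 3979 CPM, and S100a8 from 888 to 2214 CPM (1.32 ± 0.13, adjusted p = 1.87e-06). The neutrophil level rose by 1.15 log2 (exact adjusted p = 0.0302, camera adjusted p = 0.0756 with an estimated correlation). Olfm4, which marks a subset of neutrophils, rose from 15.5 to 133 CPM. Of 14 plasma cells genes, 8 rose and 0 fell, and 10 rose when adjusted over the list alone. Sdc1, the plasma cell surface marker CD138, rose from 12.5 to 32.6 CPM, and Jchain, the joining chain of secreted antibody, from 143.1 ± 50.1 to 931.3 ± 174 CPM (2.70 ± 0.26, adjusted p = 5.43e-06). The plasma cell level rose by 1.74 log2 (exact adjusted p = 0.0302, camera adjusted p = 0.0196 with an estimated correlation). In E4 library 1 the neutrophil level was 7.54, below 7.96 to 8.02 in the other 4.

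Immunoglobulin transcripts took 2.39 ± 0.263% of reads in E4, against 0.557 ± 0.0942% in E3 and 0.574 ± 0.088% in E2 (SD, n = 5 each). The heavy-chain gene Ighm rose from 1892 to 7757 CPM and the light-chain gene Igkc from 1355 to 7054 CPM in E4 against E3. The variable segment Igkv4-63 (chromosome 6, 69377944 to 69378472) was at 182, 318, 212, 221 and 176 CPM in the 5 E4 libraries and at most 1.14 CPM in the other 10, though reads of near-identical segments could have been divided between copies. Of 24 B cells genes, 4 rose and 4 fell, with Fcer2a, a low-affinity IgE receptor gene, at 80.1 CPM in E3 and 45.2 in E4 (-0.83 ± 0.09, adjusted p = 4.64e-06). Cd79a, a component of the B cell receptor, did not pass in any of the 3 comparisons.

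T cell genes went the other way. Of 27 T cells genes, 15 fell and 0 rose in E4 against E3, and 20 fell when adjusted over the list alone. Cd3e, a chain of the T cell receptor complex, fell from 170.5 ± 11.3 to 117.7 ± 9.1 CPM (-0.53 ± 0.06, adjusted p = 1.56e-05), and Cd8b1 from 139.7 to 108 CPM. The T cell level was 6.08 ± 0.15 in E4 and 6.38 ± 0.13 in E3 (exact adjusted p = 0.0603, camera adjusted p = 0.371 with an estimated correlation). E3 library 1 stood at 6.15, below 6.39 to 6.46 in the other 4. Without E3 replicate 1 the difference was -0.36 (exact adjusted p = 0.0251), and without E4 replicate 2, 9 members fell. Of 29 T and NK effector genes, 8 fell and 0 rose, with the inhibitory receptor gene Pdcd1 at 66.9 CPM in E3 and 32.0 in E4 and the natural killer receptor gene Ncr1 at 43.7 and 14.9 CPM. Under the leukocyte covariate 17 of that list fell. Ncr1 lies within 20 Mb of Apoe on chromosome 7 and was lower in E2 than in E3 too (-1.17 ± 0.12, adjusted p = 1.86e-06 by edgeR). Its fall was therefore not set apart from differences around that locus. The effector list's level did not pass (exact adjusted p = 0.071, camera adjusted p = 0.396 with an estimated correlation), and without E3 replicate 1 it differed by -0.39 (exact adjusted p = 0.0251).

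**Figure D2:**
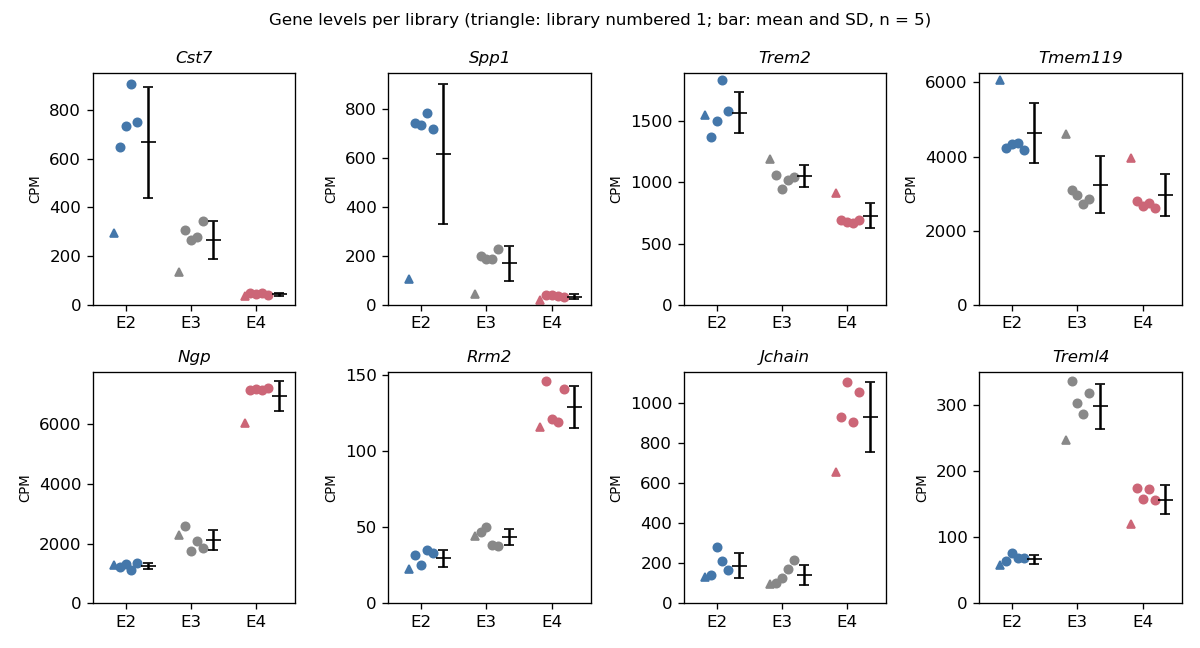
CPM of Cst7, Spp1, Trem2, Tmem119, Ngp, Rrm2, Jchain and Treml4 in each library by genotype. The triangle marks the library numbered 1 and the bars give the mean ± SD (n = 5); Ngp averaged 1257 CPM in E2, 2109 in E3 and 6938 in E4.

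The comparison of E2 with E3 asks what the protective allele does. Monocyte and neutrophil genes fell in E2. Treml4, a marker of patrolling monocytes (chromosome 17, 48264295 to 48275360), fell from 298.7 ± 33.9 CPM in E3 to 66.8 ± 6.7 in E2 (-2.16 ± 0.11, adjusted p = 3.81e-10), Ace from 210.4 to 51.9 CPM and Hp from 516.8 to 193.8 CPM. Nr4a1, which patrolling monocytes need and which cell handling also induces, fell from 441.7 to 173.3 CPM (-1.35 ± 0.09, adjusted p = 9.67e-09). It belongs to the immediate early and dissociation list, a sign of sample handling, of which 9 of 26 genes fell and 1 rose (level difference -0.22, exact two-sided adjusted p = 0.0754). Of 25 monocytes genes, 22 fell and 0 rose, and 24 fell when adjusted over the list alone. Their level was 5.79 ± 0.14 in E2 and 6.87 ± 0.15 in E3, with all 5 E2 libraries lower (exact adjusted p = 0.0754, camera adjusted p = 0.152 with an estimated correlation). The library numbered 1 was low in both genotypes, at 5.54 against 5.81 to 5.88 in E2 and at 6.61 against 6.90 to 6.99 in E3. In E4 against E3 the same list was mixed, with 4 higher and 10 lower. Chil3 rose from 713.2 to 1802 CPM there and Gngt2 fell from 198.9 to 100.3. Of 25 neutrophils genes, 23 fell in E2 and 0 rose, among them Clec4e (88.7 to 23.4 CPM), Lcn2 (277.6 to 162.0 CPM) and Trem1 (88.4 to 40.2 CPM). The neutrophil level differed by -0.82 (exact adjusted p = 0.0754, camera adjusted p = 0.176 with an estimated correlation), and 12 members fell under the leukocyte covariate. In lists chosen later, all 6 mature neutrophil receptor genes fell (median -0.79), as did 6 specific granule genes (-0.76) and 6 azurophil granule genes (-1.36). The 4 haemoglobin genes did not pass (median 0.57). Less blood left in the vessels of E2 was not tested as a source of these falls and stays open. Of 33 cell cycle genes, 18 fell and 0 rose, with Rrm2 at 43.3 CPM in E3 and 29.5 in E2. Without E2 replicate 1 or E3 replicate 3, 10 fell, and under the leukocyte covariate 0 fell by edgeR. The cell cycle level differed by -0.43 (exact adjusted p = 0.0862, camera adjusted p = 0.812 with an estimated correlation).

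Disease-associated microglia genes rose in E2. Cst7 was 666.7 ± 228 CPM in E2 (1.33 ± 0.27 against E3, adjusted p = 0.00388), Trem2 was 1568 ± 168 CPM (0.58 ± 0.09, adjusted p = 0.000333), Cd63 went from 394.2 to 633.4 CPM and Cd68 from 1120 to 1533 CPM. Of the 35 list members, 18 rose and 4 fell, and 23 rose when adjusted over the list alone. Cybb, a subunit of the phagocyte oxidase that other myeloid cells also express, fell from 881.1 to 358.1 CPM. With libraries 2 to 5 only, 26 members rose and 4 fell. The level was 8.17 ± 0.37 in E2 (difference 0.47, exact adjusted p = 0.108, camera adjusted p = 0.812 with an estimated correlation). Disease-associated minus homeostatic list level was -1.61 ± 0.56 in E2 and -1.76 ± 0.41 in E3 (SD, n = 5 each), so the rise was not set apart from a larger share of microglia. Spp1 was 614.3 ± 286 CPM in E2 (1.86 ± 0.52, adjusted p = 0.0286), with library 1 at 104 CPM and the other 4 at 718 to 780. Its adjusted p was 0.0591 and 0.0569 without E2 replicate 4 or 5, and 0.0525, 0.0615 and 0.0556 without E3 replicate 2, 3 or 4. It was 0.0815 by limma voom, 0.0804 with only the 10 libraries compared and 0.061 with the Y-linked covariate. Clec7a (171.8 and 158.2 CPM in E2 and E3) and Itgax (114.7 and 96.7 CPM) did not pass. Of 34 lysosome genes, 10 rose and 2 fell, and 14 rose when adjusted over the list alone. Glb1 went from 106.5 to 156.2 CPM and Gusb from 416.9 to 582.4 CPM. The lysosome level differed by 0.16 (exact adjusted p = 0.0862, camera adjusted p = 0.812 with an estimated correlation), and 4 members rose under the leukocyte covariate.

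Of 24 homeostatic microglia genes, 7 rose and 0 fell in E2 against E3, and 13 rose when adjusted over the list alone. Gpr34, a lysophospholipid receptor gene, was 1426 CPM in E2 and 1025 in E3 (0.48 ± 0.12, adjusted p = 0.0125), and its change was 0.11 (adjusted p = 0.648) under the leukocyte covariate. Tmem119 was 4636 ± 805 CPM in E2 and 3243 ± 779 in E3 (0.52 ± 0.15, adjusted p = 0.0277). Adjusted p for Tmem119 was 0.0795 without E2 replicate 1, 0.0641, 0.0748, 0.0755 and 0.0755 without E3 replicates 2 to 5, 0.959 under the leukocyte covariate and 0.196 under the Y-linked one. Library 1 held the highest Tmem119 of each genotype, 6070, 4613 and 3963 CPM in E2, E3 and E4. The list level differed by 0.31 (exact adjusted p = 0.0905, camera adjusted p = 0.812 with an estimated correlation). The count of members that rose was 3 without E2 replicate 1 or E3 replicate 2, 3 or 5 and 4 without E3 replicate 4. It was 12 without E3 replicate 1, 14 without E4 replicate 1, 16 with libraries 2 to 5 only and by limma voom, 1 under the Y-linked covariate and 0 under the leukocyte covariate by edgeR. P2ry12 (3243 and 2457 CPM in E2 and E3), Cx3cr1 (3931 and 3185 CPM) and Abca1 (159.8 and 139.4 CPM) did not pass. Ptprc, which encodes CD45 itself, fell from 1034 ± 149 to 706.6 ± 126 CPM (-0.55 ± 0.11, adjusted p = 0.0025), and its change was -0.32 (adjusted p = 0.208) under the leukocyte covariate.

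Several genes that differed most between E2 and E3 lay on chromosome 7 with Apoe. Slc1a5, a glutamine transporter gene (chromosome 7, 16781340 to 16798274), rose from 58.2 ± 6.1 CPM in E3 to 162.5 ± 20.4 in E2 (1.48 ± 0.10, adjusted p = 1.11e-08). Ceacam1, an adhesion receptor gene (chromosome 7, 25461707 to 25477603), fell from 404.6 ± 19.7 to 176.6 ± 3.7 CPM (-1.20 ± 0.06, adjusted p = 3.03e-10). Apoc2 fell (-2.14 ± 0.38, adjusted p = 0.000818) and Apoc4 rose (2.20 ± 0.50, adjusted p = 0.00556). With immunoglobulin and T cell receptor segments left out, 121 genes changed more than 4-fold, and 16 of them lay within 20 Mb of Apoe. Of the 14727 genes so tested, 408 lie there (Fisher's exact two-sided test, odds ratio 5.52, p = 2.25e-07). The test takes genes as independent, but some of the 16 are neighbours, such as Apoc2 and Apoc4. Others lie close together between 3756905 and 4282645, so the p-values of this test may be too small. In E4 against E3 the odds ratio was 1.2 (Fisher's exact two-sided p = 0.614), and for genes changed more than 2-fold it was 1.56 (Fisher's exact two-sided p = 0.0463), against 3.58 (p = 3.19e-09) in E2 against E3. The difference between these ratios was not tested.

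**Figure D3:**
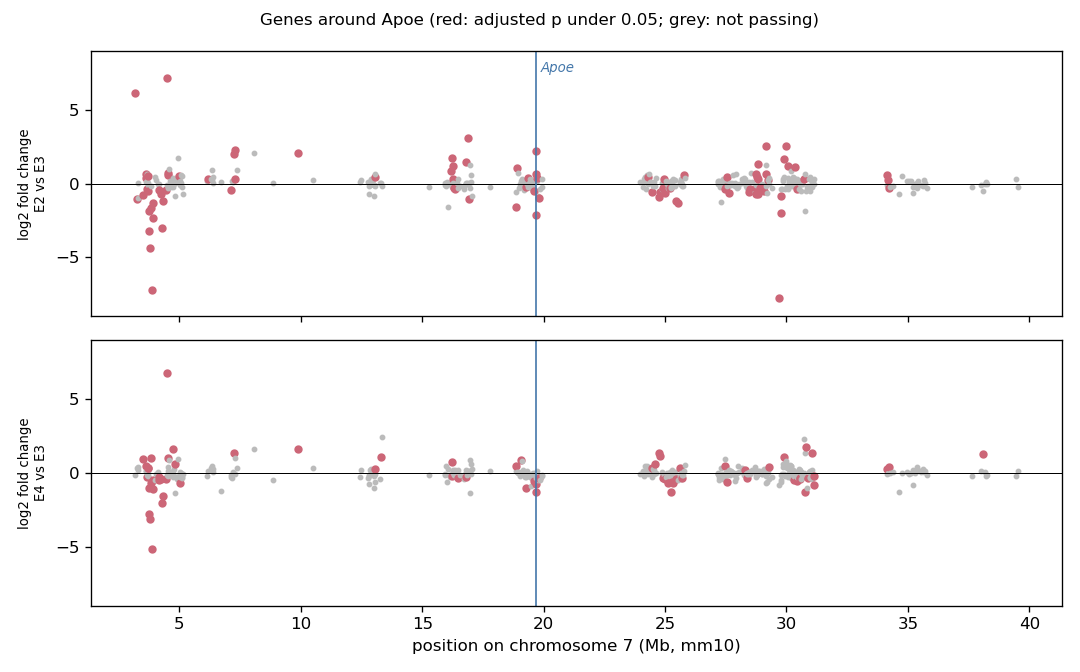
Log2 fold change of genes within 20 Mb of Apoe on chromosome 7, by position, for E2 against E3 (upper) and E4 against E3 (lower). Red marks genes past the adjusted threshold by edgeR (n = 5 libraries per genotype).

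In the direct comparison of E4 with E2, the ends of the risk range, microglial genes fell and genes of neutrophils, dividing cells and plasma cells rose. Cst7 fell by a log2 change of -3.96 ± 0.30 (adjusted p = 2.03e-07), Spp1 by -4.19 ± 0.57 (adjusted p = 0.00011) and Trem2 by -1.11 ± 0.09 (adjusted p = 9.65e-08). The cathepsin gene Ctsd went from 25076 CPM in E2 to 10240 in E4 and the phospholipase-family gene Pld3 from 521.9 to 252.1 CPM. Of the 35 disease-associated microglia genes, 28 fell and 4 rose, and 30 fell when adjusted over the list alone. The level differed by -1.45 (exact adjusted p = 0.0251, camera adjusted p = 0.256 with an estimated correlation). It was 0.0503 without E4 replicate 2, 4 or 5, where the difference stayed between -1.46 and -1.45, and the median of the members gave -0.34 (exact adjusted p = 0.244). Of 34 lysosome genes, 22 fell and 3 rose, with a level difference of -0.49 (exact adjusted p = 0.0251, camera adjusted p = 0.221 with an estimated correlation), and 8 fell under the leukocyte covariate. Of 24 homeostatic microglia genes, 17 fell and 0 rose (exact adjusted p = 0.0565, camera adjusted p = 0.575 with an estimated correlation). Under the leukocyte covariate 0 of them fell by edgeR and camera turned to higher in E4 (adjusted p = 0.0121), and without E4 replicate 1 the level differed by -0.59 (exact adjusted p = 0.0274).

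All 33 cell cycle genes rose in E4 against E2, with a level difference of 1.63, and 24 of 25 neutrophils genes rose and 0 fell, with a difference of 1.97. Ltf went from 711.3 to 3979 CPM, Chil3 from 324.8 to 1802 CPM and S100a8 from 572.6 to 2214 CPM. Of 25 monocytes genes, 20 rose and 0 fell, with a level difference of 0.82, and 7 rose under the leukocyte covariate. Of 14 plasma cells genes, 9 rose and 1 fell, with a level difference of 2.12. Each of these 4 levels had an exact adjusted p of 0.0251. With an estimated correlation, camera gave adjusted p = 0.0669 for cell cycle, neutrophils and plasma cells and adjusted p = 0.256 for monocytes. Tmem119 fell from 4636 to 2960 CPM (-0.65, adjusted p = 0.0029), and its change was 0.20 (adjusted p = 0.414) under the leukocyte covariate. Cd3e fell from 162.8 to 117.7 CPM (-0.47 ± 0.06, adjusted p = 2.64e-05). Of 29 T and NK effector genes, 13 fell and 0 rose, with the granzyme gene Gzmb lower by a log2 change of -0.98 (level difference -0.34, exact adjusted p = 0.0251, camera adjusted p = 0.575 with an estimated correlation).

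By camera with a preset correlation, 22 of 38 gene lists passed in E4 against E3, 12 in E2 against E3 and 15 in E4 against E2. With an estimated correlation only cell cycle and plasma cells passed in E4 against E3, and 0 lists passed in each of the other 2 comparisons, where 2 and 6 had an unadjusted p under 0.05 and fry called 11 and 20. By the exact test of list levels, 13, 0 and 13 lists passed after adjustment. The 0 in E2 against E3 stands beside 14 lists with an unadjusted p under 0.05, since the smallest p of 5 against 5 is 0.00794 and its smallest adjusted value there was 0.0754.

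Fold changes of E4 and of E2, both against the E3 libraries, had a low raw correlation across the 15027 genes, which are not independent replicates. Pearson's r was 0.119 and Spearman's rho -0.028. For mean log2 CPM differences, r was 0.067 and the covariance 0.023. Simulated values for unchanged groups that share the E3 libraries were 0.495 and 0.048. Observed minus simulated covariance was -0.025, so the relation lay below that of the shared libraries alone. With the E3 libraries divided between the comparisons in 20 ways, r was -0.062 on average, from -0.135 to 0.012. Both lists of changed genes use the same E3 libraries, which adds overlap in the same direction. An overlap in the same direction above that of independent lists is therefore not evidence of a common change. Genes lower in both numbered 272, where independent lists would share 102.1, and those higher in both numbered 82 against 81.2. Genes higher in E4 and lower in E2 numbered 252 against 119.2, and genes lower in E4 and higher in E2 numbered 124 against 69.5. Sharing the E3 libraries does not add overlap in opposite directions, and the source of that excess was not tested. Pa2g4, which encodes a growth-regulating RNA-binding protein, was among the genes lower in both, at 63.1 CPM in E3, 22.6 in E4 and 20.8 in E2.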

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

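The tests of residual blood, of dilution and of shared reads, and the granule, receptor and haemoglobin lists they use, were chosen after the result was seen, as was the refit with the libraries numbered 2 to 5.

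E4 had more RNA of neutrophils, dividing cells and plasma cells than E3. Among neutrophil genes the rise was steeper for those of precursors: the 6 azurophil granule genes rose by a median log2 change of 2.46, with Mpo at 185.2 CPM in E3 and 1274 in E4, and 6 receptor genes of mature neutrophils moved by a median of 0.13 (2 rose, 2 fell). Blood left in the vessels would raise mature receptor genes about as much, and the gap of 2.33 between these medians argues against ordinary blood as the whole source, while the 4 haemoglobin genes did not pass (median 0.60, adjusted p = 0.156 to 0.278 by edgeR). Bone-marrow cells among the sorted cells may be a source and stay open, since the CD45 gate would keep them: 8 early B-lineage genes had a median of 0.84, though only Rag1 passed (1.21 to 2.66 CPM), and of 9 stem-cell or megakaryocyte genes (median 0.40) Itga2b rose while Cd34 fell. Of 13 erythroid genes, 6 rose, Klf1 of red cell precursors among them, and 0 fell. Their level differed by 1.43 (exact two-sided adjusted p = 0.0302, camera adjusted p = 0.292 with an estimated correlation). Of 13 mast cells and basophils genes, 5 rose and 0 fell, and their level did not pass (exact adjusted p = 0.151). An effect of the E4 genotype on blood formation or on cell entry into the brain was not tested and also stays open.

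Dilution of microglia by other CD45+ cells, as the source of lower disease-associated microglia genes in E4 than in E3, would lower these and homeostatic genes alike, but the difference between the 2 list levels was -2.58 ± 0.38 in E4 and -1.76 ± 0.41 in E3 (SD, n = 5 each), a change of -0.82 (exact two-sided permutation p = 0.0397), with E2 at -1.61 ± 0.56. Of other cells' markers, 20 of 25 neutrophil genes rose and 15 of 27 T cell genes fell (9 without E4 replicate 2), though the T cell level did not pass (exact two-sided adjusted p = 0.0603) and camera gave adjusted p = 0.0756 and adjusted p = 0.371 for these lists with an estimated correlation. The bound for this test was set after its result was seen, a first version that asked for no overlap of libraries had left it undecided, and E3 library 1, at -2.48, lies within the E4 range of -3.26 to -2.36. These levels are means of members, and with the median the disease-associated level was not lower in E4. The list also holds genes that other sorted cells express, which need not fall alike under dilution. Added neutrophils would themselves raise neutrophil genes and lower T cell genes, so these markers do not weigh against dilution. The test therefore does not decide on dilution. The libraries numbered 1 as the source of the lower genes are argued against, since 27 list members fell in E4 with the other 4 libraries of each genotype and 26 with all 5. An effect of genotype on the microglial state may be put as a hypothesis, found and tested on the same libraries.

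A few genes were nearly absent in 1 or 2 genotypes, chosen after their values were seen with limits of 0.5 and 5 CPM: Gm3375 was at 16.4 CPM in E2 and 0.231 and 0.209 in E3 and E4, Gm10693 at 8.99 in E3 and 0.0573 and 0.253 in E2 and E4, Gm13841 at 0.103 in E2 and 7.49 and 11.3 in E3 and E4, and Eps8l1 at 0.0636 in E3 and 9.9 and 7.39 in E2 and E4. DNA of another mouse strain around the replaced locus could be a source for the 3 of these on chromosome 7, but not for Gm13841 on chromosome 5, as genes changed more than 4-fold between E2 and E3 lay within 20 Mb of Apoe with an odds ratio of 5.52 (Fisher's exact two-sided p = 2.25e-07), or 3.5 (p = 0.00331) for protein-coding genes alone. Reads shared between paralogs or pseudogenes could be another, since pseudogenes were over-represented among the same genes (odds ratio 6.33, Fisher's exact two-sided p = 1.25e-13), though less so among genes changed more than 2-fold (2.03) and under-represented among all changed genes (0.398), and Eps8l1 is protein-coding. Both stay open. No test separated an effect of APOE type on these genes from them.

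One library stood far from the other 4 in 37 of 216 groups of values, where about 1 in 20, or 10.8, would by chance. Of these, 35 were libraries numbered 1 (5 in E2, 12 in E3, 18 in E4), which points to something shared by those libraries that the labels do not name.

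In log2 list levels, E2 library 1 was at 7.5 for disease-associated microglia, 5.54 for monocytes and 4.17 for dendritic cells, each below the others. E3 library 1 was at 9.72 for homeostatic microglia and 7.04 for mouse orthologs of Alzheimer risk loci, above the others. It was below them at 7.24 for disease-associated microglia, 5.31 for interferon response, 5.03 for inflammatory cytokines and NF-kB, 4.05 for lipoprotein receptors, 6.15 for T cells, 6.61 for monocytes and 4.23 for dendritic cells. E4 library 1 was above the others at 9.78 for homeostatic microglia, 8.63 for complement and phagocytic receptors and 5.7 for mitochondrially encoded genes. It was below them at 6.52 for disease-associated microglia, 5.1 for interferon response, 8.33 for antigen presentation class II, 6.29 for B cells, 7.54 for neutrophils, 6.4 for monocytes and 4.17 for border-associated macrophages. E3 library 4 was low for TGF-beta signalling, at 3.79 against 4.17 to 4.32.

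In CPM, Tmem119 was high in the library numbered 1 of E2, E3 and E4 (6070, 4613 and 3963), and Spp1 was low in that of E2 (104) and E3 (45.2). In E4 library 1, Trem2 (910), P2ry12 (3489), Cx3cr1 (3945) and Ctsd (13321) were high, and Apoe (7.5), Cd79a (207) and Ngp (6031) were low. Ptprc was low in E3 library 1 (771) and Glb1 in E3 library 4 (90).

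As many genes as the real 2389 in E4 against E3 were called in 1 of 100 splits of the 10 libraries into 5 and 5, the real one, with 268 in the highest other. For the 5730 of E4 against E2 the count was also 1, with 2190 in the highest other. In both, the real grouping stood apart from other divisions of these libraries. This does not extend to mice, since the labels do not say whether the libraries came from separate mice. For the 2340 of E2 against E3 the count was 2, and the other split called more genes, 2666, so the real grouping did not stand apart from every other. That split put E3 library 1 in the place of E2 library 2, with both libraries numbered 1 on the same side. With E3 library 1 in the place of E2 library 3 the count was 1274, and in the place of E2 library 4 it was 0. The number 1 libraries alone therefore do not account for it. The third principal component set E2 libraries 2 and 3, at 34.8 and 38.6, apart from E2 libraries 4 and 5, at -45.8 and -16.8. This points to a structure of the samples within E2 too, whose source was not tested. For lists by camera, 4 of 100 splits, the real one among them, gave as many as the real 22 in E4 against E3. The highest other gave 24, so the real grouping did not stand apart from every other, and camera called 2 lists with an estimated correlation. Chance cannot be excluded for the 12 lists of E2 against E3 (42 splits, highest other 23) or the 15 of E4 against E2 (37 splits, highest other 23).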

How the results depend on the processing

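The refits with a Y-linked covariate, with the libraries numbered 2 to 5, without receptor segments, and the leukocyte covariate for lists were chosen after the results were seen. Genes changed in E4 against E3 numbered 4194 by limma voom, those in E2 against E3 896 with the leukocyte covariate and 1262 with the Y-linked one, and those in E4 against E2 1125 with the leukocyte covariate. That covariate is built from cells that differ by genotype, so it removes part of the genotype difference by construction, and the cause of the other moves was not tested. With an estimated correlation, camera called 2, 0 and 0 lists in E4 against E3, E2 against E3 and E4 against E2, since correlated members carry less information by construction. With the median of members, 7 list levels passed in E2 against E3, where 0 passed with the mean by the exact test (14 at an unadjusted p under 0.05). It turned the sign for disease-associated microglia in E4 against E3 (0.05) and for the integrated stress and unfolded protein response in E4 against E2 (-0.06), and the cause was not tested. The correlation of fold changes was -0.051 with the stricter filter and -0.028 by Spearman, and the cause was not tested.

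In E4 against E2 the leukocyte covariate turned the sign of Smad7 (0.12), Cd36 (-0.03), Clec12a (-0.02), Olfm1 (-0.15), Tmem119 (0.20), Cx3cr1 (0.29), Abca1 (0.07) and Ptprc (-0.05). Effective-length offsets turned that of Rps24 in E2 against E3 (-0.07) and E4 against E2 (0.02). The leukocyte covariate turned the direction of homeostatic microglia by camera in E4 against E3, E2 against E3 and E4 against E2 (adjusted p = 0.0859, 0.118 and 0.0121) and of interferon response in E2 against E3 (adjusted p = 0.494). The cause of these turns was not tested.

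Leaving out each library in turn gave 1801 to 2806, 1639 to 3058 and 4931 to 6191 genes, 20 to 22, 11 to 15 and 14 to 18 lists, and 8 to 19, 0 to 0 and 10 to 15 list levels, in E4 against E3, E2 against E3 and E4 against E2. The 8 came without E3 replicate 3 or 4 and the 19 without E4 replicate 1. The correlation ran from 0.122 to 0.216. Of named gene fold changes in these runs, 7590 kept their side of the threshold, 207 lost it, 55 gained it and 8 moved. In the other settings the numbers were 6419, 200, 92 and 21, with 10 turned.

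With the replicate number as a block, 2792, 2805 and 5960 genes and 22, 12 and 16 lists passed. Residuals of libraries with the number 1 correlated at 0.24, 0.36 and 0.31, and those of the other equal numbers at -0.22 to 0.20. Of the 15 such pairs 6 were above 0.1, and 9 of 30 best matches had their own number, so the numbers as a whole were not taken as pairs. The planned covariate of Xist was not run, since Xist is not among the transcripts counted.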

Other observations

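The counts of variable segments and the leukocyte covariate for lists were chosen after the results were seen. Erythroid genes rose in E4 against E3. Klf1, a transcription factor of red cell precursors, rose from 3.2 to 34.2 CPM (3.41 ± 0.48, adjusted p = 0.000165). Of 13 erythroid cells genes, 6 rose and 0 fell (8 rose adjusted over the list alone), with a level difference of 1.43 (exact two-sided permutation test, adjusted p = 0.0302, camera adjusted p = 0.292 with an estimated correlation). Of 13 mast cells and basophils genes, 5 rose and 0 fell, among them Gata2, a precursor transcription factor gene (7.7 to 25.7 CPM). Their level did not pass (exact adjusted p = 0.151), and without E4 replicate 1 it differed by 1.20 (exact adjusted p = 0.0476). Of 25 border-associated macrophages genes, 8 rose and 1 fell (exact adjusted p = 0.17), with 5 higher without E3 replicate 5 or E4 replicate 2 or 3 and 13 without E4 replicate 1, where the level differed by 0.60 (exact adjusted p = 0.0355).

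Sterol genes moved too in E4 against E3, as did mitochondrially encoded genes, a measure of library quality whose source was not tested. Of 24 cholesterol biosynthesis genes, 5 rose and 1 fell, with Sqle higher by 0.71 and Fdps by 0.47. Its level rose by 0.19 (exact adjusted p = 0.0464, from 0.0532 to 0.0838 in 8 runs that leave out 1 library, camera adjusted p = 0.396 with an estimated correlation). Of 13 mitochondrially encoded genes, 11 fell and 0 rose, with mt-Nd2 at 72.3 CPM in E3 and 36.2 in E4 (level difference -0.70, exact adjusted p = 0.0464, from 0.0532 to 0.0754 in 8 such runs, camera adjusted p = 0.371 with an estimated correlation). Mitochondrial reads held 0.164 ± 0.00535% in E4 and 0.284 ± 0.0634% in E3. Of 38 interferon response genes, 13 fell and 0 rose, among them Zbp1 and Ifitm3 (-0.50 and -0.52). Their level did not pass (exact adjusted p = 0.0794), and without E3 replicate 1 it differed by -0.27 (exact adjusted p = 0.0251). Of 40 mouse orthologs of Alzheimer risk loci, 10 fell and 0 rose, led by Ace (-0.89) and Ms4a4a (-0.78), with a level difference of -0.15 (exact adjusted p = 0.0302, and 0.0548, 0.0603 and 0.0548 without E3 replicates 3, 4 and 5, camera adjusted p = 0.199 with an estimated correlation).

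Genes that rose and fell in the other lists in E4 against E3 were as follows. They were 5 and 2 for antigen presentation class II (3 higher in 8 runs that leave out 1 library), 3 and 5 for immediate early and dissociation, 5 and 4 for lipid droplet and fatty acid handling, 0 and 4 for complement and phagocytic receptors (8 lower without E4 replicate 1, 7 without E2 replicate 4), 7 and 3 for glycolysis and hypoxia, 1 and 0 for oxidative phosphorylation and 0 and 2 for cytosolic ribosomal proteins (5 lower without E2 replicate 4). They were 3 and 1 for integrated stress and unfolded protein response, 1 and 3 for TGF-beta signalling (5 lower without E4 replicate 1), 2 and 2 for lipoprotein receptors, 1 and 3 for neighbours of Apoe on chromosome 7, and 3 and 3 for dendritic cells. For cell types outside the CD45 gate they were 2 and 3 for neurons, 2 and 2 for astrocytes, 0 and 1 for oligodendrocyte lineage and 0 and 7 for endothelial and mural cells (4 lower without E4 replicate 3). Choroid plexus and ependymal cells and sex-chromosome genes had 0 and 0 by edgeR. Among these lists the astrocytes level passed, at 1.21 in E4 and 0.67 in E3 (0.54, exact two-sided adjusted p = 0.0302, and 0.0548, 0.0603 and 0.0548 without E3 replicates 3, 4 and 5, camera adjusted p = 0.58 with an estimated correlation). So did that of neighbours of Apoe on chromosome 7 (-0.12, exact adjusted p = 0.0464, from 0.0548 to 0.0754 in 7 runs that leave out 1 library, camera adjusted p = 0.396 with an estimated correlation). Median and camera direction differed in sign for lipoprotein receptors (median 0.10, camera down) and sex-chromosome genes (0.03, down), median and mean for lipid droplet and fatty acid handling (0.05 and -0.05) and glycolysis and hypoxia (-0.03 and 0.08).

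In E2 against E3, 5 of the antigen presentation class II genes rose and 0 fell, with H2-DMa, a class II loading factor gene, at 365.5 CPM in E3 and 495.2 in E2. Only 2 or 3 rose in 7 runs that leave out 1 library. Of interferon response genes 1 rose and 10 fell (6 lower without E2 replicate 1 or E3 replicate 5), of inflammatory cytokines and NF-kB 3 and 11 (5 higher without E4 replicate 1), of immediate early and dissociation 1 and 9 and of glycolysis and hypoxia 2 and 11 (6 lower without E2 replicate 1 or 5 or E3 replicate 2, 7 without E3 replicate 3). C3, a complement protein gene, fell from 162.6 to 46.2 CPM, while 10 complement and phagocytic receptors genes rose and 5 fell. Dgat2, a triglyceride synthesis gene, fell from 40.4 to 17.0 CPM, and lipid droplet and fatty acid handling had 3 higher and 7 lower (4 lower without E3 replicate 2). Border-associated macrophages had 5 higher and 0 lower (2 to 8 higher in runs that leave out 1 library, 8 without E3 replicate 2 and 2 without E3 replicate 3), and T cells 1 and 3 (5 lower without E3 replicate 1). None of these list levels passed the exact test after adjustment. Median and mean differed in sign for LXR targets and cholesterol efflux (0.08 and -0.12), mouse orthologs of Alzheimer risk loci (0.04 and -0.08), integrated stress and unfolded protein response (0.06 and -0.02), erythroid cells (0.10 and -0.35) and neurons (0.03 and -0.17).

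In E4 against E2 the level of glycolysis and hypoxia rose by 0.21 (13 higher, 6 lower), that of cholesterol biosynthesis by 0.28 (11 and 2) and that of erythroid cells by 1.94 (6 and 0), and that of mitochondrially encoded genes fell by 1.37 (0 and 12), each with an exact adjusted p of 0.0251. Camera gave adjusted p = 0.723, 0.523, 0.523 and 0.479 with an estimated correlation. Antigen presentation class I had 0 higher and 9 lower (-0.18, exact adjusted p = 0.0251, and 0.0503 without E4 replicate 2, 4 or 5, camera adjusted p = 0.523 with an estimated correlation). Median and mean differed in sign for inflammatory cytokines and NF-kB (-0.12 and 0.02), dendritic cells (-0.02 and 0.06) and choroid plexus and ependymal cells (0.05 and -0.07). Of the genes named whatever their p, Clec7a and Itgax fell (-0.75 and -1.24), as did reads assigned to mouse Apoe (-1.43 ± 0.20, adjusted p = 2.82e-05). Cx3cr1 fell by -0.40 (adjusted p = 0.0224, and 0.0574 without E2 replicate 1 and 0.0549, 0.0601, 0.0506 and 0.058 without E4 replicates 2 to 5). Abca1 fell by -0.41 (adjusted p = 0.0205, and 0.0592 and 0.0544 without E4 replicate 2 or 4). Ptprc rose by 0.31 (adjusted p = 0.0372, and 0.111, 0.108 and 0.102 without E2 replicate 1, 4 or 5 and 0.0576, 0.0657, 0.0776 and 0.0681 without E4 replicates 2 to 5).

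Of 174 immunoglobulin variable segments tested, 29 reached 20 CPM in all 5 libraries of E4, against 3 in E2 and 2 in E3, and 7 did so in E4 and in no library of another genotype. In 1 library of a genotype only, the numbers were 27, 37 and 27 in E2, E3 and E4. The limit was not scaled to the immunoglobulin share of reads, 0.574% in E2, 0.557% in E3 and 2.39% in E4. The higher counts in E4 were therefore not set apart from that higher total. For 1 segment, Igkv4-63, the gap was wider than that of the total, at 176 to 318 CPM in E4 and at most 1.14 CPM elsewhere. Its reads could have been divided between near-identical copies, and the segments as a set were not compared in this way. Y-linked genes were expressed in all 15 libraries, with Ddx3y at 57.2 to 83.3 CPM and Uty at 11.3 to 23.7 CPM, so male cells were present in each, and the labels give no sex.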
